A study of Mus musculus with 12 samples.

How the data were processed

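RNA from mouse TT2 embryonic stem cells was measured on Affymetrix whole-transcript arrays in 4 genotypes, which were wild type, G9a knockout, GLP knockout and the double knockout of both genes. Each genotype had 3 arrays, 12 in all. Per the labels' protocols, cells were grown in medium with serum and LIF, total RNA was extracted with Trizol, and biotinylated sense-strand cDNA was prepared with the whole-transcript labelling kit. Each array was placed in its group by its own label. The labels state neither whether the 3 arrays of a genotype came from separate cultures nor which clones were used, so the p-values measure only the spread between these arrays, which may be technical.

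The values used were the deposited log2 probe set values, which the authors made with RMA (background correction, normalization between arrays and summary of the probes of a set) and Partek, per the submitters' processing notes, which give no versions and no role for either tool. The array model, probe set definition, annotation version and genome build are not given in the sources used here. The table held 22309 probe sets, 1 per Ensembl gene identifier, with values from 2.64 to 13.26 on the log2 scale. Array medians lay close together, quartiles differed slightly between arrays, and genes were not centred. RMA pulls low signals towards a floor, so fold changes of weakly expressed genes are understated. Each of the 12 columns was matched to a sample.

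No gene symbols could be attached. The files do not pair the identifiers with names, and the RefSeq gene table used here (assembly GRCm38.p6, 49997 genes) lists an Ensembl identifier for 0 of its genes, so 0 identifiers matched. The 28 gene lists fixed before the data were examined, the cell type markers and the levels of the targeted genes were therefore not analysed here, and the knockouts were not checked against the labels. All probe sets were tested, without a filter, and are called genes below. The rule fixed beforehand took the genes with the largest rises and falls among those past the threshold whose knockout arrays all lay beyond all wild type arrays. Without names, it was limited to 2 identifiers that rose and 2 that fell, taken as the first-ranked genes of the knockout comparisons in order. Other genes are described without an identifier.

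A linear model with 1 mean per genotype was fitted to each gene over all 12 arrays in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, without a block for replicate number. It had 8 residual and 3.69 prior degrees of freedom, and the median residual SD after moderation by eBayes was 0.13 on the log2 scale. There were 7 contrasts, which were the 6 pairs of genotypes and the departure of the double knockout from the sum of the single knockouts (double minus G9a minus GLP plus wild type, the interaction). A moderated F test asked whether genotype mattered at all. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. Tests were two-sided. Counts of calls that also differed at least 2-fold are given. The number of arrays limits the precision. The median standard error of a difference between 2 genotypes was 0.10 on the log2 scale.

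The fit was tested on simulated data for all 22309 genes, of which 200 were changed. For G9a against wild type it recovered 68.7% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold. The corresponding shares were 79.1%, 98.5% and 100% for GLP and 71.6%, 95.5% and 98.5% for the double knockout. Unchanged genes made up 16 of 194 calls for G9a, 13 of 198 for GLP and 12 of 189 for the double knockout. Because the 3 knockouts were compared with the same wild type arrays, 50 sets of unchanged groups that shared simulated wild type arrays were drawn and analysed alike. Every simulated array had the moderated residual spread of its gene, pooled over the genotypes, so any larger spread of the real wild type arrays was left out.

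Alternatives fixed before the data were examined were a second quantile normalization, centring arrays on their medians, leaving out the dimmest genes, fitting only the arrays compared, the replicate number as a block, array weights, a trended and robust variance prior, unmoderated contrasts with the pooled residual variance, a threshold of 0.01 and leaving out each array in turn. A covariate for the spread of each array's values, and the grouping of genes by the contrasts they passed, were chosen after seeing the data.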

Results

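The data describe RNA levels in TT2 cells, a mouse embryonic stem cell line, and in derivatives lacking G9a, GLP or both. G9a and GLP are related enzymes that methylate histone H3 on lysine 9 and work together in a complex. The series title names gene silencing by Polycomb repressive complex 2 as its subject, and the comparisons ask which genes changed level when either or both enzymes were absent. Each of the 4 genotypes had 3 arrays, and 22309 genes were measured as RMA log2 values. The first principal component held 36.8% of the variance and set the wild type arrays, with scores from -41.2 to -28.0, apart from all 9 knockout arrays. The second held 19.2% and set the 3 G9a knockout arrays apart from the GLP and double knockout arrays. In the moderated F test of limma, 2227 genes (9.98%) differed among the genotypes at an adjusted p under 0.05.

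**Figure D1:**
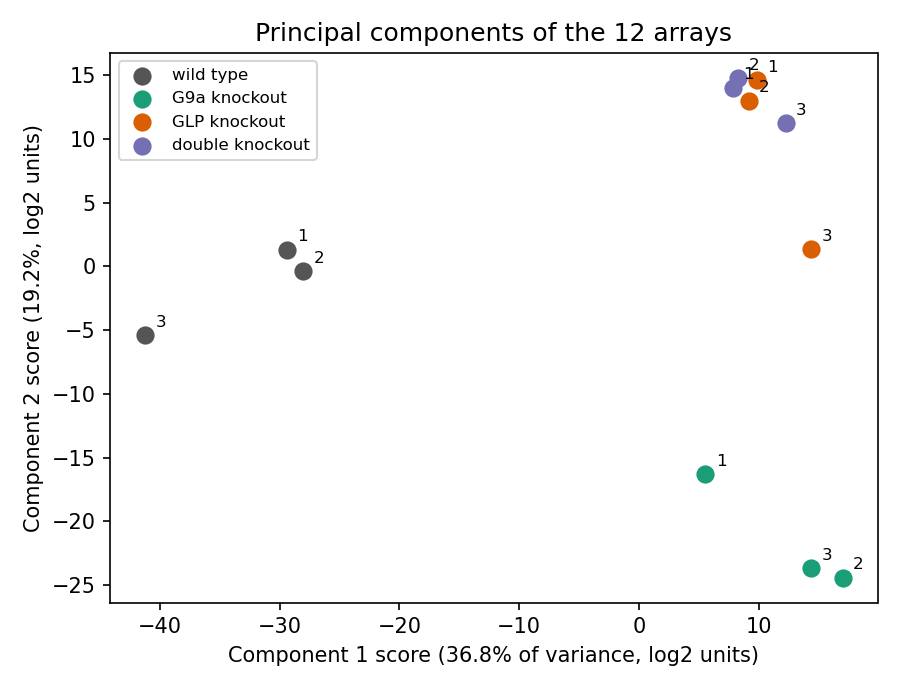
Scores of the 12 arrays on the first and second principal components of the log2 values, in log2 units, with points coloured by genotype and numbered by replicate. Wild type arrays lie at the left on component 1, which holds 36.8% of the variance, and G9a knockout arrays lie apart from GLP and double knockout arrays on component 2, which holds 19.2%.

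The G9a knockout was compared with wild type cells to find genes whose level differed when G9a was absent. Large changes were mostly rises. Of the genes called at least 2-fold different, 278 were higher and 86 were lower in the knockout (76.4% higher), and of those at least 4-fold different, 57 were higher and 7 lower. The strongest riser, ENSMUSG00000079349_at, stood at 3.63 ± 0.19 (SD, n = 3) on the log2 scale in wild type cells and at 9.36 ± 0.13 (SD, n = 3) in the knockout, a 53.02-fold rise. Next came ENSMUSG00000079350_at, which rose from 3.13 ± 0.17 to 8.84 ± 0.06 (SD, n = 3 each), or 52.0-fold. The wild type levels of ENSMUSG00000079349_at and ENSMUSG00000079350_at lay at percentiles 6.35 and 1.08 of all genes and were not shown to be above background, so the folds of both genes in all 3 knockouts are ratios of RMA values with an uncertain baseline. The largest fall was that of ENSMUSG00000068457_at, from 7.89 ± 0.15 to 4.02 ± 0.07 (SD, n = 3 each), or 14.6-fold. The knockout level lay at percentile 11.7 of all genes and was not shown to be above background, so this fold is a ratio of RMA values too. Whether this fall followed the deletion or another difference of this cell line, such as lost chromosomal material, was not tested. ENSMUSG00000030717_at fell from 10.52 ± 1.09 to 7.41 ± 0.43 (SD, n = 3 each), a log2 change of -3.11 with a standard error of 0.565 (limma adjusted p = 0.00492). At any size, 1147 genes were called higher and 1130 lower by limma (2277 in all). The adjusted p was 1.07e-10 for ENSMUSG00000079349_at, with a log2 change of 5.73 and a standard error of 0.12, and 2.81e-08 for ENSMUSG00000068457_at, with a log2 change of -3.87 and a standard error of 0.14. The total fell to 1461 without G9a replicate 2, to 1330 without G9a replicate 3, to 1459 with only the arrays compared and to 1388 with unmoderated contrasts.

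In the GLP knockout, 221 genes were called at least 2-fold higher and 63 at least 2-fold lower than in wild type cells (77.8% higher), and 56 against 2 genes passed 4-fold. Both strongest risers of the G9a knockout rose here too, ENSMUSG00000079349_at to 9.76 ± 0.20 (SD, n = 3), or 70.1-fold, and ENSMUSG00000079350_at to 9.27 ± 0.21 (SD, n = 3), or 70.4-fold. Neither differed between the GLP and G9a knockouts past the threshold (limma adjusted p = 0.133 for ENSMUSG00000079349_at and 0.0871 for ENSMUSG00000079350_at). ENSMUSG00000030717_at, which fell in the G9a knockout, had the largest fall here, from 10.52 ± 1.09 to 8.10 ± 0.21 (SD, n = 3 each), a log2 change of -2.42 (limma adjusted p = 0.0247). Its wild type arrays spread from 9.80 to 11.78, and its call was lost without wild type replicate 3 and without any 1 of the 3 GLP arrays. The log2 change was -1.794 without wild type replicate 3, and -2.369, -2.545 and -2.355 without GLP replicates 1, 2 and 3. ENSMUSG00000068457_at, which fell in the G9a knockout, stood at 8.17 ± 0.26 (SD, n = 3) here, a log2 difference of 0.28 from wild type with an adjusted p of 0.32. At any size, limma called 797 genes higher and 694 lower (1491 in all). The total was 893 without GLP replicate 1, 940 without GLP replicate 3, 959 with only the arrays compared and 760 with unmoderated contrasts.

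In the double knockout, 221 genes were called at least 2-fold higher and 71 at least 2-fold lower than in wild type cells (75.7% higher), and 57 against 1 passed 4-fold. ENSMUSG00000079349_at reached 9.86 ± 0.08 (SD, n = 3), a 75.2-fold rise, and ENSMUSG00000079350_at reached 9.34 ± 0.14 (SD, n = 3), a 74.0-fold rise. Both stood above their levels in the G9a knockout, by 0.50 (limma adjusted p = 0.0457) for ENSMUSG00000079349_at and 0.51 (0.0388) for ENSMUSG00000079350_at on the log2 scale. ENSMUSG00000068457_at stood at 8.05 ± 0.22 (SD, n = 3), 0.16 above wild type on the log2 scale, with an adjusted p of 0.652. ENSMUSG00000030717_at stood at 8.83 ± 1.16 (SD, n = 3), a log2 difference of -1.69 that did not pass the threshold (adjusted p = 0.115) and was -1.06 without wild type replicate 3. At any size, limma called 726 genes higher and 615 lower (1341 in all). The total was 884 without double knockout replicate 1, 754 without double knockout replicate 3, 754 with unmoderated contrasts and 2172 with array weights.

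**Figure D2:**
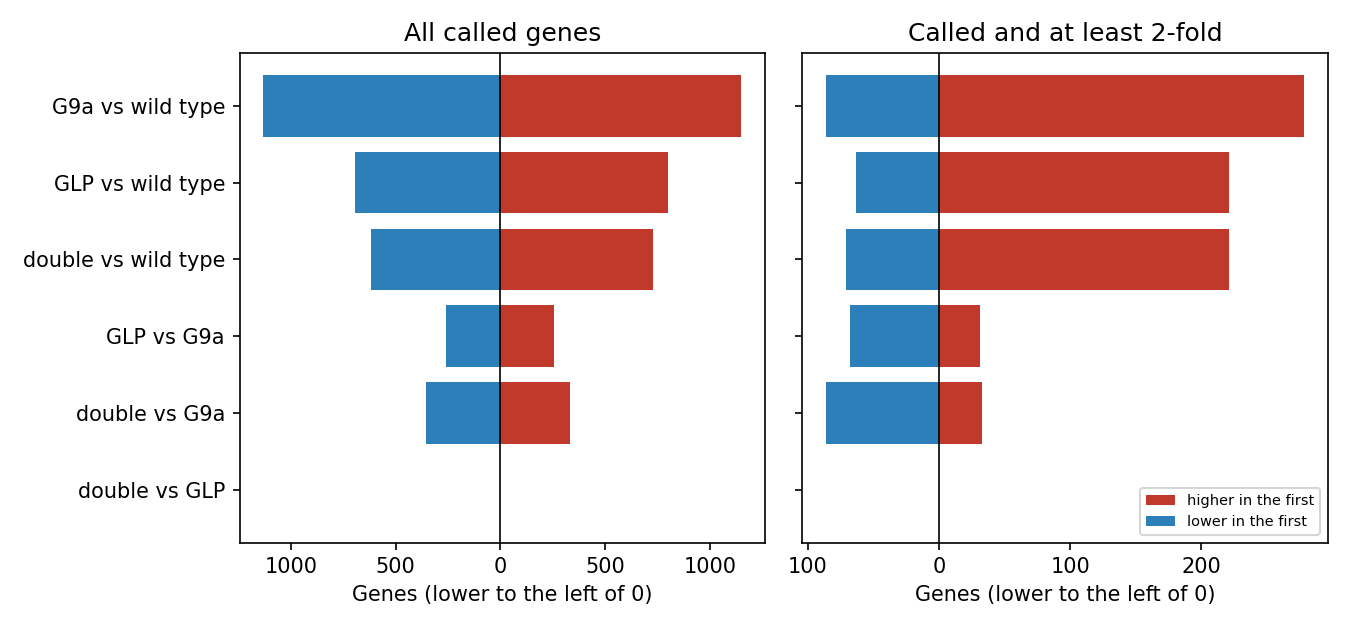
Numbers of genes called by limma at an adjusted p under 0.05 in each pair of genotypes, higher to the right of 0 and lower to the left, for all calls and for calls of at least 2-fold. Rises outnumber falls among the larger changes of all 3 knockouts against wild type, and no gene was called between the double and GLP knockouts.

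**Figure D3:**
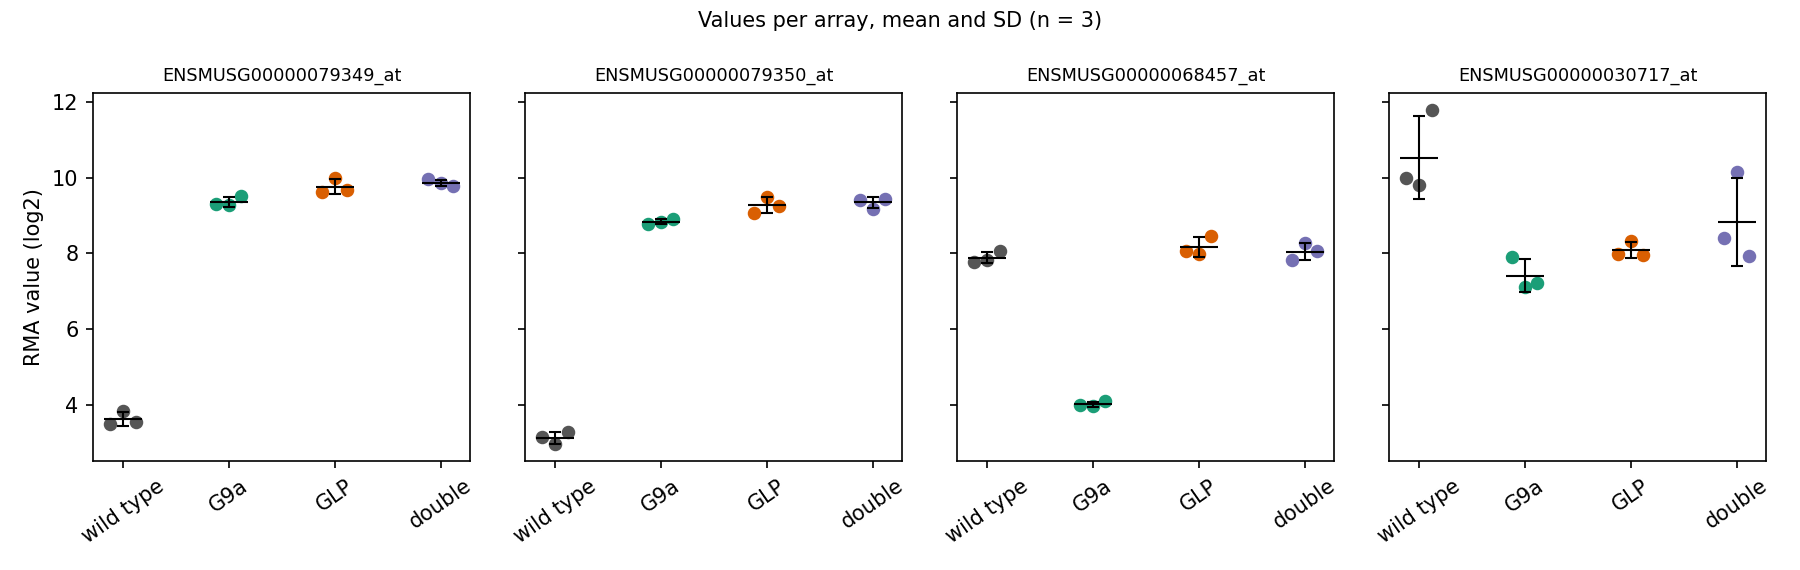
RMA log2 values of 4 genes on the 12 arrays, with points for arrays and bars for the mean and SD of 3 arrays. ENSMUSG00000079349_at and ENSMUSG00000079350_at are high in all 3 knockouts, ENSMUSG00000068457_at is low in the G9a knockout, and ENSMUSG00000030717_at spreads widely within the wild type and double knockout groups.

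The 3 knockouts shared many of their changes. In total, 739 genes were called in the same direction in all 3, with 398 higher and 341 lower. The shared risers had median log2 changes of 0.83 in the G9a, 0.91 in the GLP and 0.90 in the double knockout, and the shared fallers of -0.62 in each. Changes of at least 2-fold in all 3 were held by 126 shared risers and 25 shared fallers. Between the G9a and GLP knockouts, 497 rises and 457 falls were shared, where independent lists of these sizes would share 41.0 and 35.2. GLP and double knockouts shared 569 rises and 481 falls, against 25.9 and 19.13. In the simulations of unchanged groups that shared simulated wild type arrays, no more than 1 gene was ever called alike in a pair. Unchanged groups give few calls at all, so a low overlap was set in advance. It does not show how much overlap the shared wild type arrays add when many genes are called. The simulated arrays also spread less than the real wild type arrays, so the simulated overlap may be too low. Across genes, which are not independent replicates, log2 changes correlated at r = 0.763 between the G9a and GLP knockouts, 0.718 between the G9a and double knockouts and 0.925 between the GLP and double knockouts. Unchanged groups gave r near 0.50. The covariances were 0.0789, 0.0736 and 0.0881, against 0.00825, 0.00827 and 0.00826 in the simulation. The spread between the wild type arrays themselves gave a covariance of 0.0121, which left 0.0668, 0.0615 and 0.0760. The 3 wild type arrays were not divided between the comparisons, so part of the excess overlap may come from sharing them. A difference of the wild type cells from the knockout lines other than the deletions would also appear as shared changes, and was not tested. The shared count was 483 without double knockout replicate 3, 460 with only the arrays compared and 401 with unmoderated contrasts.

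**Figure D4:**
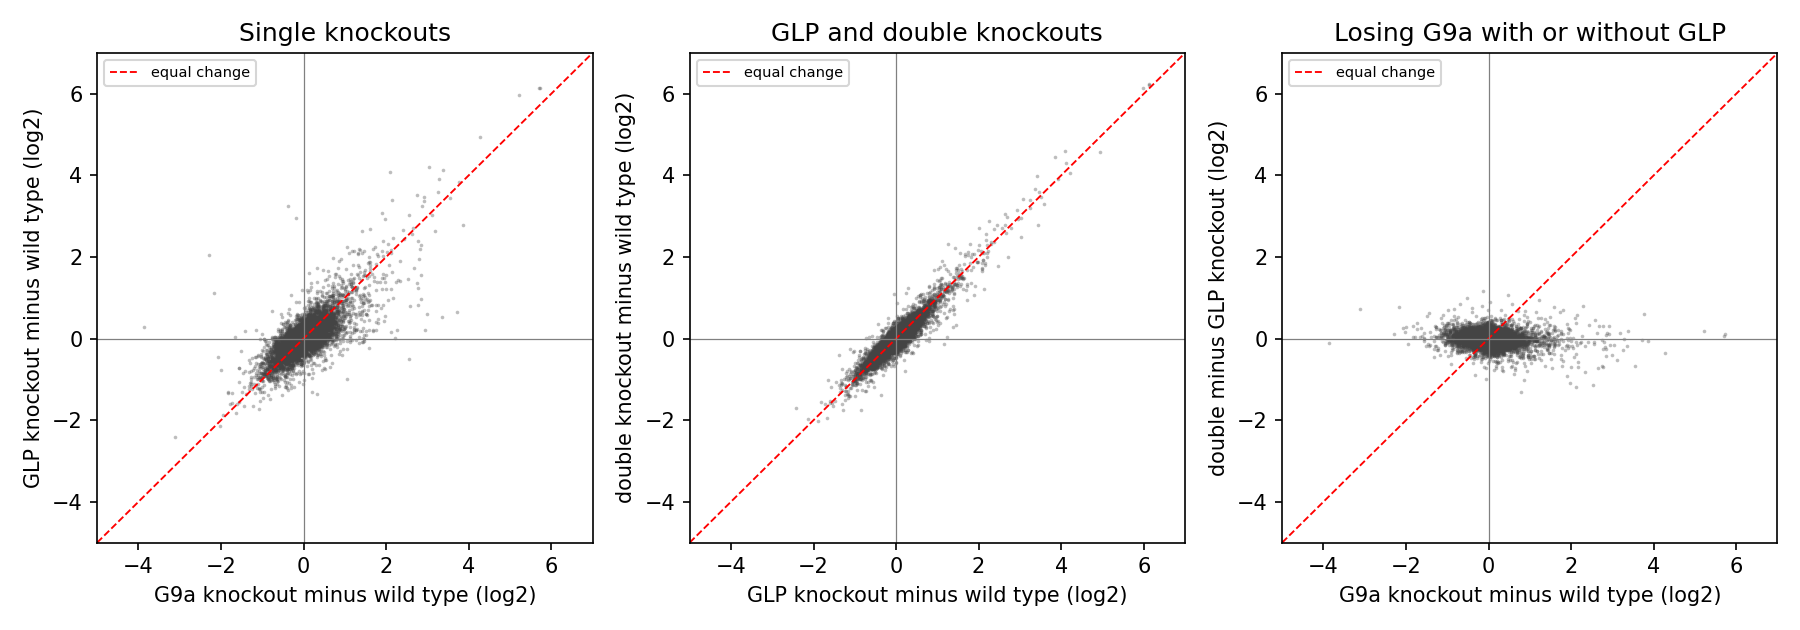
Log2 changes of 22309 genes, each point a gene, for the GLP against the G9a knockout, the double against the GLP knockout, and the double minus GLP difference against the G9a knockout change, with a dashed line of equal change. The changes of the GLP and double knockouts lie along the line (r = 0.925), and the double minus GLP difference is small beside the G9a change and correlates weakly with it (r = -0.133).

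The GLP and G9a knockouts were compared directly to find where the enzymes differed. Compared with the G9a knockout, the GLP knockout had 31 genes at least 2-fold higher and 68 at least 2-fold lower, and the double knockout had 33 higher and 86 lower. A group of 289 genes differed in the G9a knockout from each of the 3 other genotypes. Of these, 164 were higher in the G9a knockout (median log2 change 0.84 from wild type, with 0.03 in the GLP knockout) and 125 were lower (-0.61, with -0.02 in the GLP knockout). The genes were picked for G9a levels apart from the other genotypes in these same data, so the gap between these medians partly follows from that choice. Against wild type, 26 of the 289 were also called in the same direction in the GLP knockout and 14 in the double knockout, and 6 were called in the opposite direction in 1 or both. ENSMUSG00000068457_at had the largest fall in this group, and its source in this cell line was not tested. A smaller group of 67 genes was called in both the GLP and double knockouts and differed from the G9a knockout in the same direction. Its 43 higher genes had median log2 changes of 1.18 in the GLP, 1.31 in the double and 0.24 in the G9a knockout, and 15 of them were also called higher in the G9a knockout while 3 were called lower there. The lower G9a median partly follows from the choice of genes too. As for the larger group, a difference between cell lines other than the deletions was not tested. Across all genes, limma called 516 between the GLP and G9a knockouts (256 higher, 260 lower) and 690 between the double and G9a knockouts (334 higher, 356 lower). The 289 became 124 without G9a replicate 3, 98 and 128 without GLP replicates 1 and 2, 174 and 192 without double knockout replicates 1 and 3, 124 with only the arrays compared, 547 with array weights and 109 with unmoderated contrasts. The 67 became 27 without G9a replicate 3, 24 and 37 without GLP replicates 1 and 2, 33 with only the arrays compared, 151 with array weights and 20 with unmoderated contrasts. The 516 became 342 and 192 without G9a replicates 2 and 3, 139 and 207 without GLP replicates 1 and 2, 281 with only the arrays compared, 1047 with array weights and 168 with unmoderated contrasts. The 690 became 333 without G9a replicate 3, 372, 397 and 402 without double knockout replicates 1, 2 and 3, 1338 with array weights and 292 with unmoderated contrasts.

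The double and GLP knockouts were compared to ask what losing G9a changed in cells already lacking GLP. No gene was called by limma. At an unadjusted p under 0.05, 581 genes (2.604%) differed, fewer than the 1115 that chance would give, and the lowest adjusted p was 0.175. The unmoderated contrasts also called 0, while a fit of only these arrays called 1 gene, array weights 3, and leaving out wild type replicate 3 called 1. The 95% interval of the difference lay within 2-fold for 99.05% of genes and within 1.5-fold for 93.0%, and for 213 genes a 2-fold difference was not excluded. These shares include weakly expressed genes, whose fold changes RMA understates. GLP and double arrays did not overlap for 7.52% of genes, where chance gives 10%. Across genes, the double minus GLP difference correlated at r = -0.133 with the G9a knockout change, with which it shares no array, where simulated unchanged groups gave 0.000783. The simulated arrays were drawn independently, whereas residuals of real same-numbered arrays correlated from -0.286 to 0.316. Whether such array effects alone gave this r was not tested.

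The interaction contrast asked whether the double knockout showed the sum of the single changes. For the 398 shared risers the single changes summed to a median of 1.73 on the log2 scale, while the double knockout showed 0.90, and the double minus GLP difference had a median of 0.00 (quartiles -0.09 and 0.11). Of these risers, 207 were called below the sum, and of the 341 shared fallers 164 were called above it. The direction of these calls was set by picking genes called alike in all 3 knockouts, given that GLP and double changes were alike. They restate the likeness of the GLP and double knockouts and are no separate evidence. For 5 of the 207, among them ENSMUSG00000079349_at and ENSMUSG00000079350_at, the sum lay above 13.26, the highest value on any array, so their falling below it was fixed by the scale. Over all genes limma called 845, with 372 above the sum and 473 below it. The total was 554 without wild type replicate 1, 541 and 446 without G9a replicates 2 and 3, 474 without GLP replicate 3, 403 and 553 without double knockout replicates 1 and 2, 1423 with array weights and 214 with unmoderated contrasts.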

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

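The test of knockout RNA in a wild type array was fixed before its result was seen, leaving out each array was planned but applied to a gene group defined after seeing the data, and the other tests of explanations in this part were chosen only afterwards. The interaction contrast, which sets the double minus GLP difference against the G9a minus wild type difference, passed the threshold for 845 genes. It speaks of losing G9a in cells without GLP only if the double knockout arrays hold what their labels say, which was not checked. All 4 identified genes were among them, with interaction values of -5.63 for ENSMUSG00000079349_at, -5.63 for ENSMUSG00000079350_at, 3.75 for ENSMUSG00000068457_at and 3.84 for ENSMUSG00000030717_at. These genes were picked for large changes against wild type, and their double minus GLP differences were 0.10, 0.07, -0.12 and 0.73, none called. The interaction values are thus mostly the G9a change with its sign reversed and are no separate evidence. For ENSMUSG00000030717_at, the value of 11.78 in wild type replicate 3 enters both. For ENSMUSG00000079349_at and ENSMUSG00000079350_at the sum of the single changes needed levels of 15.49 and 14.97, above the highest value on any array (13.26), so a negative value was fixed by the scale. A further 4 genes were called in opposite directions in the G9a knockout and in both the GLP and double knockouts.

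The double knockout showed no called change beyond the GLP knockout. A ceiling of the signal was argued against by 155 genes that rose at least 2-fold in the G9a knockout and stood mid-scale in the GLP knockout, whose median double minus GLP difference was -0.0541 (upper quartile 0.13) where at least 0.71 was needed, although for 5 of the 845 genes past the interaction threshold the sum lay beyond the scale. GLP and double arrays holding the same material remains open, since 7.52% of genes had no overlap between them, below the median of 9.89% and the highest of 16.04% among the 9 other splits, and the same would follow if the double knockout expressed its genes like the GLP knockout. The biological explanation, that G9a has little effect on RNA levels once GLP is gone, could therefore not be separated from it, because the levels of the targeted genes were not read.

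The second pattern was the 289 genes that differed in the G9a knockout from the 3 other genotypes. A single G9a array as the whole cause was argued against, since the lowest count with 1 G9a array left out was 124 (without G9a replicate 3), although it was 98 and 128 without GLP replicates 1 and 2, and 174 and 192 without double knockout replicates 1 and 3. Unequal spread of the arrays' values was argued against by a count of 351 with that spread as a covariate. A difference between cell lines other than the deletion cannot be told apart from an effect of G9a, since the labels name 0 clones of the G9a knockout, and for the fall of ENSMUSG00000068457_at a chromosome or part of one lost in this line was not excluded. A loss of G9a that matters only while GLP is present stays open as the biological explanation, untested.

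The third pattern was that wild type replicate 3 lay apart from wild type replicates 1 and 2, with 248 genes over 2-fold from the mean of its group mates. Knockout RNA in this array was argued against, since 141 genes changed at least 2-fold in all 3 knockouts stood at a median of -0.0220 of the way from the other wild type arrays to the knockouts (upper quartile 0.183), where at least 0.1 was needed. The same position came to 0.113 and 0.100 for wild type replicates 1 and 2, whose reference includes replicate 3. Both reached the value set for knockout RNA, so reaching it does not by itself show such RNA. The test argues only against more knockout RNA in replicate 3 than in replicates 1 and 2. Unequal spread was argued against by an SD of 2.09 within the range of the 11 other arrays. The third principal component held 11.19% of the variance. Its scores were positive only for wild type replicate 3 (18.34), G9a replicate 2 (7.73), GLP replicate 3 (12.42) and double knockout replicate 2 (18.05). In that order, these arrays also had the lowest array weights (0.439, 0.535, 0.572 and 0.602). A factor common to these arrays was not tested, and the replicate number does not single them out. A different culture or processing day cannot be told apart from other causes, since the labels name 0 batches or days. No biological explanation was tested.

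Other splits of the arrays into groups of the same sizes were analysed alike. Of 100 splits of the 12 arrays, 1, the real one, gave as many genes in the F test as the 2227 observed. The highest other gave 2086 and kept all wild type and all G9a arrays together. Random labelling of the arrays was thus argued against as its source. A chance difference between single cultures was not excluded, because the 3 arrays of a genotype may not be separate cultures. For the interaction, 2 of 100 splits gave as many as the 845 observed, and the highest other gave 1306. This count does not bear on chance, because most splits mix genotypes with large differences and only 9 of the other splits called any gene, while the highest kept the wild type arrays in their role but gave the G9a arrays the role of the double knockout and most double knockout arrays that of G9a, and so tested another contrast. The 10 splits of each pair of genotypes are too few to reach a share under 0.05. The real and highest other counts were 2277 and 0 for G9a against wild type, 1491 and 0 for GLP against wild type, 1341 and 0 for the double knockout against wild type, 516 and 9 for GLP against G9a, 690 and 0 for the double knockout against G9a, and 0 and 0 for the double knockout against GLP, where all 10 splits gave as many. In the 5 comparisons with calls, only 1 split, the real one, gave as many.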

How the results depend on the processing

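The alternatives were fixed before the data were examined, except the covariate for array spread and the 2 gene groups, chosen after seeing the data. No direction of a named gene reversed, and calls of at least 2-fold against wild type stayed within 1.5 times under every setting. Total counts moved more, and the cause was not tested except that a stricter threshold passes fewer genes. Leaving out an array did not always lower a count. Without wild type replicate 3, calls rose from 516 to 688 for GLP against G9a and from 690 to 934 for the double knockout against G9a. With unmoderated contrasts and with a threshold of 0.01, respectively, the counts were 1388 and 1020 for G9a, 760 and 603 for GLP and 754 and 598 for the double knockout against wild type, 168 and 125 for GLP against G9a, 292 and 213 for the double knockout against G9a, 214 and 202 for the interaction, 1072 and 973 for the F test, 401 and 304 for genes shared by the 3 knockouts, 109 and 76 for genes that differed in the G9a knockout from the 3 others, and 20 and 14 for genes called in the GLP and double knockouts and different from G9a. With only the arrays compared they were 1459 for G9a and 959 for GLP against wild type, 281 for GLP against G9a, 1 for the double knockout against GLP, 460 shared, 124 for the G9a group and 33 for the GLP and double group. With array weights they were 2172 for the double knockout against wild type, 1047 for GLP against G9a, 1338 for the double knockout against G9a, 3 for the double knockout against GLP, 1423 for the interaction, 547 for the G9a group and 151 for the GLP and double group.

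Leaving out each array gave 1330 to 2301 calls for G9a, 893 to 1516 for GLP and 754 to 1368 for the double knockout against wild type, 139 to 688 for GLP against G9a, 333 to 934 for the double knockout against G9a, 0 to 1 for the double knockout against GLP, 403 to 1027 for the interaction, 1505 to 2133 for the F test, 483 to 729 shared, 98 to 343 for the G9a group and 24 to 87 for the GLP and double group. ENSMUSG00000030717_at lost its call in the GLP knockout with unmoderated contrasts and at 0.01. The call was also lost without wild type replicate 3 (log2 change -1.79) and without any 1 of the 3 GLP arrays. In the double knockout the gene gained a call with array weights (-1.68) and without double knockout replicate 2 (-2.35), while its change there was -1.06 without wild type replicate 3.

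With the replicate number as a replicate block, counts were 2262 for G9a, 1499 for GLP and 1337 for the double knockout against wild type, 504 for GLP against G9a, 698 for the double knockout against G9a and 806 for the interaction. The labels do not say that a number marks shared material. Residuals of 9 of 18 same-numbered pairs correlated above 0.1 (from -0.286 to 0.316), and 6 of 12 arrays correlated best with an array of their own number, so the numbers were not taken to pair the arrays. Not run were the mean over probe sets of a gene and the test of unnamed probe sets, since each gene had 1 probe set and all were tested, and the gene lists and targeted genes, for want of names. Signal over background was not analysed here. When genes were put into 5 equal bins by mean level, G9a against wild type had calls for 1.30% of the dimmest bin and 17.8% of the brightest.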

Other observations

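Among the genes called in opposite directions, 3 were lower in the G9a knockout and higher in the GLP and double knockouts, and 1 was the converse. For 2 of the 3 the differences were at least 2-fold in each knockout. The first stood at 6.99 ± 0.03 (SD, n = 3) on the log2 scale in wild type cells, with changes of -2.29 in the G9a, 2.05 in the GLP and 2.16 in the double knockout. The second stood at 6.34 ± 0.30 (SD, n = 3), with changes of -2.16, 1.12 and 1.90. In the G9a knockout they stood at 4.70 ± 0.20 and 4.18 ± 0.18 (SD, n = 3 each), levels not shown to be above background, so the sizes of both falls are uncertain. Both genes were chosen after their values were seen. As for ENSMUSG00000068457_at, the labels name 0 clones of the G9a knockout, so a difference between cell lines other than the deletion, such as lost chromosomal material, cannot be told apart from an effect of G9a on these genes. The rises of both genes in the GLP and double knockouts carry the same doubt. A difference of the wild type cells or of those lines other than the deletions could give these rises too, and neither was tested.

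The standard deviation of the log2 values within an array was 2.02 to 2.05 in 4 arrays, 1 of each genotype (wild type replicate 2, G9a replicate 2, GLP replicate 3 and double knockout replicate 2), and 2.08 to 2.10 in the other 8.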
